A study of Homo sapiens with 6 samples.

How the data were processed

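RNA was sequenced from Caco2 cells with a non-target hairpin (NT, 3 libraries) or a hairpin against PLEKHA7 (shP7, 3 libraries), both stably expressed after lentiviral infection and puromycin selection, per the labels' protocols. The labels name a pair of library kits, TruSeq and SMART-Seq v4, without saying which was used for which library. The deposited table holds raw read counts per gene for the 6 libraries, per the file headers. HTSeq, DESeq2 and the build hg19 are named in the submitters' processing notes; the aligner, the annotation, the strand setting and all versions are not given in the sources used here, and no coordinates are reported. The same table holds the authors' comparison as log2 fold changes with standard errors on the log2 scale, and the p-values and adjusted p-values of the authors, per the file headers. Of 20457 deposited log2 fold changes, 99.8% lay within 0.01 of those from DESeq2 with a normal prior on the fold changes and 25.4% within 0.01 of those without it, so they are shrunken values. They are quoted only where named as the authors'.

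The table lists 25375 entries. In 6 of them a symbol is listed a second time with identical counts, and these were left out, which left 25369 genes, 4912 of them without a count in any library. A gene identifier was lacking for 514 genes, which kept their symbols and took 0.379% to 0.404% of the counts. Symbols are those of the table, several of them older ones such as GPR98, CYR61 and the HIST genes; list members were matched through current and older symbols. Libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 21.4 to 45.1, so none was counted as a repeat of another. The 10 most abundant genes took 4.53% to 5.46% of the counts.

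Genes with low counts were removed with filterByExpr of edgeR (version 4.0.16, in R 4.3.3), which left 15202 genes, and libraries were scaled by TMM, with factors of 0.975 to 1.01. The main test, chosen before the data were examined, was edgeR's quasi-likelihood test with robust dispersion (glmQLFit and glmQLFTest) of shP7 against NT without a covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic. CPM values use the TMM-scaled library sizes. PLEKHA7 was also compared by an exact permutation test.

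The replicate numbers were checked for pairing before the fits were compared. Deviations from the group means correlated at 0.36, 0.28 and 0.37 between libraries of the same number and at −0.27 to −0.08 between libraries of different numbers, so the numbers were taken to pair the libraries; the labels do not say what a number shares. The biological coefficient of variation was 13.0% without and 6.70% with the number as a block. The blocked fit is reported as an alternative.

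Before the data were examined, 31 gene lists were fixed, covering junctions, the cytoskeleton, microRNA genes, intestinal lineages, signalling, metabolism, other cell types and RNA quality. The 13 mitochondrially encoded genes are not among the table's genes, and the RNA quality list had 4 tested genes, under the minimum of 5; both lists went untested. The other 29 were tested with camera of limma (version 3.58.1) at its preset correlation of 0.01, and with an estimated correlation and with fry as alternatives. Counts of members are given over all genes tested and adjusted over the list alone. The genes named are PLEKHA7, the 10 largest rises and the 10 largest falls among changed genes with a mean of at least 1 CPM and no overlap between groups, and up to 4 members of each list: the 2 with the smallest adjusted p in each direction, or the 2 most abundant where none passed. Some of the genes this rule takes are not reported here. Others are said to be chosen after their values were seen.

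Alternatives were DESeq2's size factors, DESeq2 (version 1.42.0), limma-voom, no filter beyond 1 count over the libraries, a filter of 1 CPM in 3 libraries, a test against a fold of 1.5 (glmTreat), the replicate block, and each library or each replicate number left out. Families of genes with the same letters before the first digit or hyphen of the symbol, with at least 10 tested members, were tested with camera after the lists.

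For 3' UTR words, the basic transcript with the longest 3' UTR was taken per gene from GENCODE v29, which follows another build than the authors' and served for sequence alone. Transcript length and GC were found for 95.7% of the tested genes, and 13012 had a 3' UTR of at least 50 bases. The presence of each of 16242 words of 7 bases found in at least 50 genes was related to the log2 fold change after adjustment for 3' UTR length, GC and expression, in Python 3.11.15 with numpy 2.4.6. Genes were matched to that annotation through the gene identifiers of a RefSeq table (GRCh38.p14), used for names alone.

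The calculations were tested on simulated counts for the comparison of shP7 with NT, with 15202 genes of which 200 were changed. Without pair effects, edgeR recovered 52.2%, 80.6% and 97.0% of the changes of 1.5-fold, 2-fold and 4-fold, with 4.40% false calls, and DESeq2 53.7%, 79.1% and 95.5% with 12.6% false calls. With pair effects as fitted, edgeR without the block recovered 34.3%, 70.1% and 90.9% with 0% false calls, and with the block 68.7%, 85.1% and 100% with 6.60% false calls. DESeq2 recovered 43.3%, 77.6% and 95.5% there, with 0% false calls. Each setting was drawn once, with dispersions from the trend over genes. Genes that vary more than that trend were not simulated, so the rates of false calls may differ in the real data. Of simulated lists, 2 of 2 shifted by 0.3 on the log2 scale were called both with the preset and with the estimated correlation. Of 26 unshifted lists 0 were called. Genes were drawn independently and without pair effects there, so false calls of lists whose members vary together were not tested. In the real data the estimated correlation reached 0.84, in the histone list.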

Results

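PLEKHA7 is a protein of the zonula adherens, the belt of cell-cell contacts that joins epithelial cells near their apical side, and it is known to hold parts of the microRNA machinery there. The study asked which RNAs change when this protein is depleted. It used Caco2, an established line from a human colon adenocarcinoma that forms polarised epithelial sheets in culture. RNA sequencing covered 3 libraries of cells with a non-target short hairpin RNA (NT) and 3 libraries of cells with a hairpin against PLEKHA7 (shP7), numbered 1, 3 and 4 in each group. Reads on genes came to 42838143, 54084629 and 36331157 counts in NT replicates 1, 3 and 4, and to 48642456, 51365322 and 53443124 counts in shP7 replicates 1, 3 and 4. Between 17837 and 18522 genes had at least 1 count per library. Libraries of the same number varied together, so a second fit with the replicate number as a block (the blocked fit) is given where it changed a call. The labels name 1 hairpin per group and do not say whether the libraries came from separate cultures. The p-values of single genes therefore measure the spread between these libraries, which may be technical. Those of camera at its preset correlation compare the genes of a list with other genes, and measure mainly the spread between genes.

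PLEKHA7 (gene identifier 144100) fell to 48.9% of its NT level in shP7 cells. It stood at 41.8 ± 4.0 CPM (counts scaled by library size; SD, n = 3) in NT and at 20.5 ± 1.4 CPM (SD, n = 3) in shP7, from 1532 to 2023 counts and from 1001 to 1083 counts per library. The log2 fold change was −1.03 ± 0.11 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00361). Each shP7 library held 48.9%, 51.6% or 46.6% of the level of the NT library with the same number. An exact two-sided permutation test of the 3 against 3 values gave p = 0.1, the smallest this design allows. The authors' deposited table gave a log2 fold change of −0.92 ± 0.11 (SE) and an adjusted p of 9.47e-15. With replicate 1 left out of both groups the adjusted p was 0.0726, and with replicate 3 left out of both it was 0.062. Over all left-out libraries the log2 fold change stayed between −1.11 and −0.98.

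**Figure D1:**
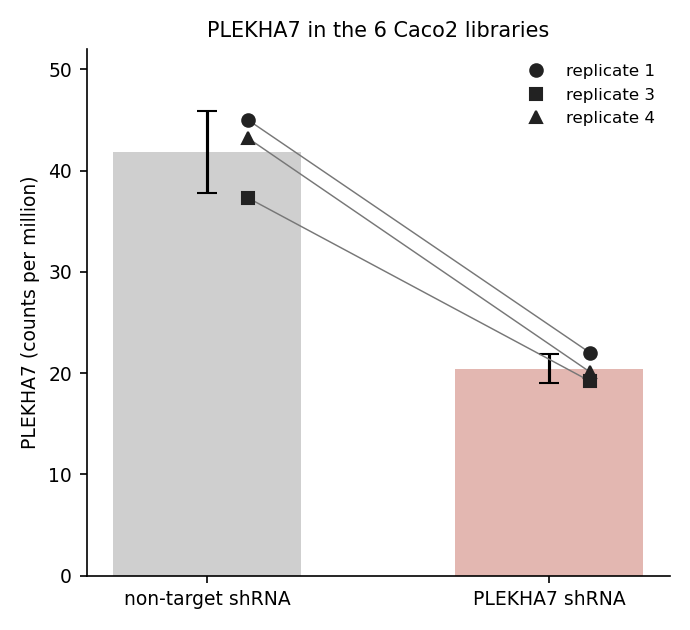
PLEKHA7 in CPM (y axis) in the 3 NT and the 3 shP7 libraries; bars are means, error bars are SD (n = 3), points are libraries and lines join libraries with the same replicate number. The 3 shP7 libraries lay between 19.2 and 22.0, all below the NT libraries at 37.3 to 45.0.

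Among genes with a mean of at least 1 CPM, the transcripts that rose most with PLEKHA7 depletion include those of brush-border enzymes and fibrinogen chains, and those that fell most include a cell cycle inhibitor, focal adhesion adaptors and surface receptors. MEP1A, the alpha subunit of the brush-border protease meprin, rose from 0.424 ± 0.219 to 3.05 ± 0.841 CPM (SD, n = 3; log2 fold change 2.82 ± 0.37 SE, adjusted p = 0.0102). SI, the disaccharidase sucrase-isomaltase, rose by 2.08 ± 0.38 on the log2 scale (adjusted p = 0.0339). The fibrinogen beta and gamma chains, FGB and FGG, rose by 2.19 ± 0.35 and 2.07 ± 0.22 (adjusted p = 0.0279 and 0.00435). CACHD1, a relative of calcium channel subunits, rose from 8.25 ± 1.14 to 30.0 ± 5.57 CPM (log2 fold change 1.86 ± 0.16, adjusted p = 0.00232). The other large rises among these genes were SHISA6, the adhesion receptor GPR98, the sodium chloride cotransporter SLC12A3, the neurotrophin BDNF and the synaptic scaffold PCLO, with log2 fold changes of 1.62 to 1.89. The call of FGB ended without a filter on low counts (adjusted p = 0.104) and that of SI with limma-voom (adjusted p = 0.0537).

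On the other side, GPRC5A, a retinoic acid-induced receptor, fell from 288.9 ± 71.7 to 78.2 ± 24.9 CPM (SD, n = 3; log2 fold change −1.88 ± 0.24 SE, adjusted p = 0.0119). CDKN2B, the cyclin-dependent kinase inhibitor p15, fell from 28.0 ± 5.93 to 7.92 ± 4.00 CPM (log2 fold change −1.82 ± 0.31, adjusted p = 0.034). HSPB8, a small heat shock protein, fell from 75.4 ± 17.2 to 25.6 ± 9.92 CPM (log2 fold change −1.56 ± 0.26, adjusted p = 0.032). Among genes with a mean of at least 1 CPM, CCDC71L had the largest fall (log2 fold change −2.11 ± 0.37, adjusted p = 0.0283), followed by the chemokine receptor CXCR4 (−1.92 ± 0.33, adjusted p = 0.0241). The focal adhesion adaptors TGFB1I1 and LIMS2 fell with log2 fold changes of −1.56 and −1.59, the protease CTSE with −1.79, MDGA1 with −1.69 and the interferon-induced IFIT2 with −1.53. Without a filter on low counts GPRC5A, CDKN2B and HSPB8 no longer passed (adjusted p = 0.0798, 0.134 and 0.155). LIMS2 did not pass with DESeq2's size factors or limma-voom (adjusted p = 0.0508 and 0.0667), nor CTSE with a filter of 1 CPM in 3 libraries (adjusted p = 0.0531).

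In total, 286 of the 15202 genes tested changed (edgeR quasi-likelihood test, adjusted p under 0.05): 74 rose and 212 fell. Their median change was 1.54-fold. At least 2-fold changes numbered 21 upwards and 32 downwards. The blocked fit called 2865 genes (1153 higher and 1712 lower), or 18.8% of those tested, including each of the 286 with the same sign. Counts of list members in the blocked fit stand against this 18.8%. The share of lower genes among the calls was 59.8% in place of 74.1%. DESeq2 called 819 genes, 285 of the 286 among them. Against a fold of 1.5, 1 gene passed, CACHD1. The authors' deposited table held 810 genes with an adjusted p under 0.05 (244 higher and 566 lower), of which 282 were among the 286 with the same sign. Without the block the count rested on every library but 1: it was 131 without NT replicate 1, 12 without NT replicate 3, 90 without NT replicate 4, 92 without shP7 replicate 1 and 95 without shP7 replicate 4, and it was 0 (1781 genes at an unadjusted p under 0.05), 6 and 30 with replicate 1, 3 or 4 left out of both groups. Of the 38 genes besides PLEKHA7 that passed among those taken by the rule for named genes, 22, 4 and 15 still passed without NT replicate 1, 3 or 4, and 15, 32 and 15 without shP7 replicate 1, 3 or 4. With replicate 1, 3 or 4 left out of both groups, 0, 4 and 4 of these 38 still passed. With pair 1, 3 or 4 left out of the blocked fit, a check chosen after seeing the data, the count of genes was 2004, 2011 and 2086. Of those genes, 1840, 1864 and 1904 were shared with the full blocked fit at the same sign.

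**Figure D2:**
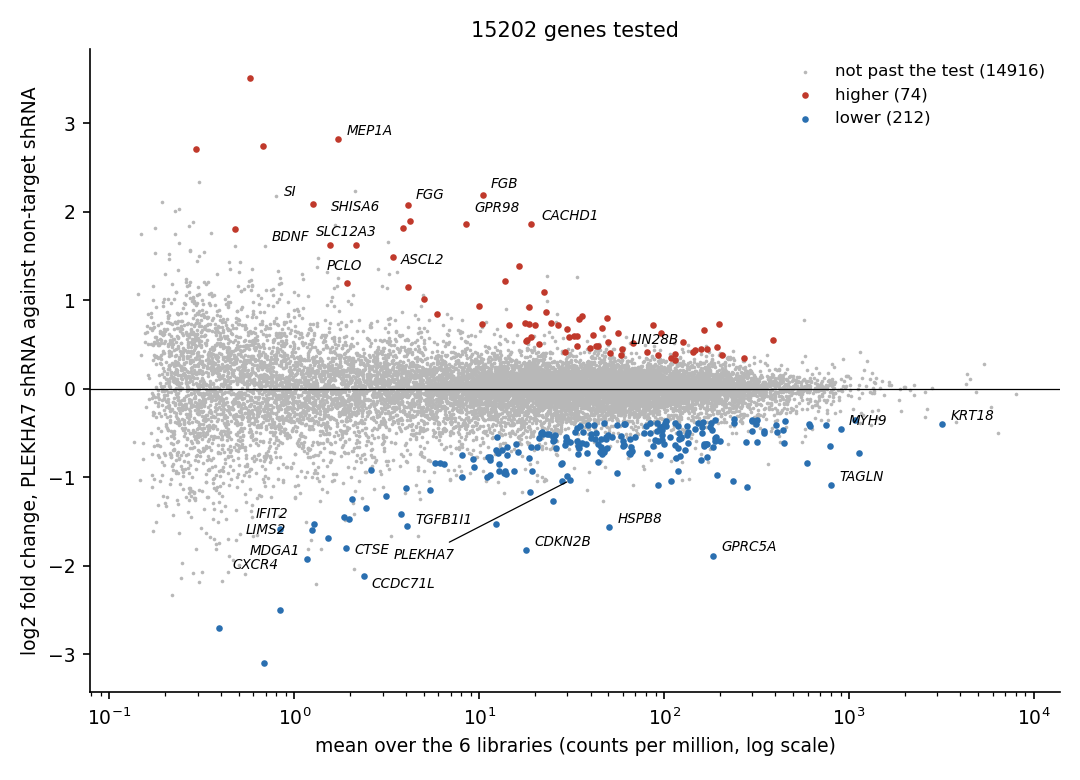
Log2 fold change of shP7 against NT (y axis) against mean level over the 6 libraries in CPM (x axis, log scale) for the 15202 genes tested by edgeR without the block. The 74 genes that rose are in red, the 212 that fell in blue, and PLEKHA7, the genes with the largest changes at a mean of at least 1 CPM and a few list members are named.

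Genes of the actin cytoskeleton lay below their NT levels almost throughout. Of 29 measured genes of the actin and RhoA list, 28 had a log2 fold change below 0, with a median of −0.22. MYH9, the heavy chain of nonmuscle myosin IIA, fell from 1044 ± 18.4 to 760.6 ± 14.9 CPM (SD, n = 3; log2 fold change −0.46 ± 0.07 SE, adjusted p = 0.0127) and was the only member past the test over all genes. Adjusted over the list alone, 12 members fell, and in the blocked fit 22 fell and 0 rose. The list stood lower than other genes in camera (adjusted p = 3.72e-09), but not with a correlation estimated between its genes (adjusted p = 0.597 with an estimated correlation).

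Of the junction genes, none of the 24 measured in the adherens junction and PLEKHA7 complex list passed edgeR's test over all genes (10 at an unadjusted p under 0.05; 2 passed in DESeq2), and 1, CDH1, fell adjusted over the list alone. CDH1, which encodes E-cadherin, went from 1598 ± 68.1 to 1270 ± 88.0 CPM (SD, n = 3; log2 fold change −0.33 ± 0.08 SE, adjusted p = 0.0608), and CTNNA1, which encodes alpha-catenin, had −0.18 ± 0.07 (adjusted p = 0.209). CDH1 fell in DESeq2 (adjusted p = 0.00953) and without a filter on low counts (adjusted p = 0.0403). Both fell in the blocked fit (adjusted p = 1.79e-05 and 0.00533), in which 5 members of this list rose and 8 fell, without a direction for the list as a whole (camera adjusted p = 0.48 with the block and 0.414 without). Among 24 tight junction genes 0 passed edgeR's test over all genes and 0 adjusted over the list alone (7 at an unadjusted p under 0.05; 0 passed in DESeq2). TJP1, which encodes ZO-1, had a log2 fold change of −0.21 ± 0.07 (adjusted p = 0.146) and F11R, which encodes JAM-A, −0.09 ± 0.07 (adjusted p = 0.609). In the blocked fit TJP1 fell (adjusted p = 0.00193), 6 tight junction genes were lower and 1 was higher, and the list was lower in camera (adjusted p = 0.0434 with the block, 0.0642 without; adjusted p = 0.49 with an estimated correlation in the blocked fit). Without shP7 replicate 3 the unblocked p was 0.0243.

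Of 15 desmosome and keratin genes, KRT18, the keratin of simple epithelia, fell from 3625 ± 222 to 2741 ± 184 CPM (SD, n = 3; log2 fold change −0.40 ± 0.08 SE, adjusted p = 0.0386). It was the only member past the test over all genes, 2 fell adjusted over the list alone, and 7 fell in the blocked fit. The list was lower in camera (adjusted p = 0.0187; adjusted p = 0.638 with an estimated correlation). Leaving out NT replicate 3, shP7 replicate 1 or shP7 replicate 4 ended that call (camera adjusted p = 0.054, 0.0811 and 0.0564).

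The lists of mesenchymal genes, matrix genes and YAP targets had median log2 fold changes of −0.43, −0.22 and −0.23, with few members past the test. TAGLN, an actin-binding protein of contractile cells, fell from 1095 ± 148 to 513.3 ± 106 CPM (SD, n = 3; log2 fold change −1.09 ± 0.15 SE, adjusted p = 0.0127), and the growth factor TGFB2 fell from 39.7 ± 3.37 CPM with a log2 fold change of −0.99 ± 0.12 (adjusted p = 0.00939). These were the 2 of 17 measured mesenchymal genes past the test over all genes; 6 fell adjusted over the list alone and 8 in the blocked fit, with a list median of −0.43. Camera gave the list an adjusted p of 1.83e-06 downwards (adjusted p = 0.597 with an estimated correlation). CYR61, a YAP and TEAD target, fell by 0.66 ± 0.14 on the log2 scale (adjusted p = 0.0478), but not with limma-voom (adjusted p = 0.0543) or a filter of 1 CPM in 3 libraries (adjusted p = 0.0528). With TGFB2 it made 2 of 19 YAP and TEAD targets past the test over all genes; 5 fell and 1 rose adjusted over the list alone, and 9 fell and 2 rose in the blocked fit. The YAP and TEAD list was lower in camera (adjusted p = 6.51e-04; adjusted p = 0.638 with an estimated correlation).

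None of 30 matrix genes passed edgeR's test over all genes (12 at an unadjusted p under 0.05; 8 passed in DESeq2), while 8 fell and 2 rose adjusted over the list alone, and 13 fell and 5 rose in the blocked fit. FN1, which encodes fibronectin, had a log2 fold change of −0.50 ± 0.16 (adjusted p = 0.165) and fell in the blocked fit (adjusted p = 6.28e-04) and in DESeq2 (adjusted p = 0.0291). The matrix list was lower in camera (adjusted p = 0.0382; adjusted p = 0.638 with an estimated correlation), and without NT replicate 3, shP7 replicate 1 or shP7 replicate 4 its p was 0.236, 0.308 and 0.0564.

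Among immediate-early genes, KLF6 fell from 81.7 ± 14.3 to 49.1 ± 4.68 CPM (SD, n = 3; log2 fold change −0.73 ± 0.13 SE, adjusted p = 0.0283) and JUN from 23.2 ± 1.09 to 14.7 ± 2.55 CPM (log2 fold change −0.66 ± 0.14, adjusted p = 0.0431). They were the 2 of 23 members past the test over all genes; 5 fell and 1 rose adjusted over the list alone, and 7 fell and 1 rose in the blocked fit. Camera placed the list lower (adjusted p = 0.0104; adjusted p = 0.638 with an estimated correlation), but not without shP7 replicate 4 (adjusted p = 0.256). JUN also belongs to the list of growth and transformation genes linked to PLEKHA7, where LIN28B, an RNA-binding protein that blocks let-7 maturation, rose from 50.0 ± 2.26 to 68.4 ± 7.04 CPM (log2 fold change 0.45 ± 0.09, adjusted p = 0.0402). Of the 16 measured genes of that list, 1 rose and 1 fell over all genes, 1 rose and 1 fell adjusted over the list alone, and 6 rose and 1 fell in the blocked fit. Camera gave that list no direction without the block (adjusted p = 0.356) and placed it higher with it (adjusted p = 0.0234; adjusted p = 0.43 with an estimated correlation in the blocked fit).

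MEP1A, SI, FGB and FGG, 4 of the 10 largest rises at a mean of at least 1 CPM, belong to the enterocyte and hepatic lists. Of 30 measured enterocyte genes, 4 rose and 0 fell: MEP1A, SI and, chosen after their values were seen, the lactase gene LCT (log2 fold change 1.20, adjusted p = 0.0436) and the peptidase gene DPP4 (0.44, adjusted p = 0.0447). Adjusted over the list alone 4 rose and 1 fell, and in the blocked fit 11 rose and 6 fell. The list was higher in camera (adjusted p = 6.51e-04; adjusted p = 0.638 with an estimated correlation). Among 17 genes of fetal liver and hepatocytes the 3 fibrinogen chains rose, with FGA going from 12.9 ± 1.93 to 24.4 ± 2.35 CPM (SD, n = 3; log2 fold change 0.92 ± 0.13 SE, adjusted p = 0.0135). Adjusted over the list alone 6 rose, and in the blocked fit 8 rose and 2 fell. Camera placed the hepatic list higher (adjusted p = 2.64e-04; adjusted p = 0.597 with an estimated correlation).

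ASCL2, a transcription factor of intestinal stem cells, rose from 1.78 ± 0.446 to 5.03 ± 0.417 CPM (SD, n = 3; log2 fold change 1.48 ± 0.22 SE, adjusted p = 0.0137). It was the only one of 22 stem cell and Wnt target genes past the test over all genes; 3 rose adjusted over the list alone and 7 in the blocked fit. The stem cell list was higher in camera (adjusted p = 0.0386; adjusted p = 0.597 with an estimated correlation), but not without shP7 replicate 4 (adjusted p = 0.166). CHGB, a granule protein of enteroendocrine cells, rose by 1.01 ± 0.22 on the log2 scale (adjusted p = 0.0478), but not with a filter of 1 CPM in 3 libraries (adjusted p = 0.0551). It was 1 of 10 measured genes of the secretory lineages and also the 1 that passed adjusted over the list alone; in the blocked fit 3 rose and 1 fell. Camera gave the secretory list no direction (adjusted p = 0.359).

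All 15 measured replication-dependent histone genes had a log2 fold change above 0, with a median of 0.28. None passed edgeR's test over all genes or adjusted over the list alone (8 at an unadjusted p under 0.05; 0 passed in DESeq2), and 13 rose in the blocked fit. HIST1H1E had 0.31 ± 0.13 (adjusted p = 0.29) and HIST1H1C 0.21 ± 0.12 (adjusted p = 0.44); both rose in the blocked fit (adjusted p = 1.26e-04 and 0.00227). Histone genes are near-identical copies, and how the counting divided their shared reads is not given in the sources used here. The histone list was higher in camera (adjusted p = 6.34e-06; adjusted p = 0.638 with an estimated correlation). None of 28 cell cycle genes passed edgeR's test over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05; 1 passed in DESeq2), and 2 rose and 3 fell in the blocked fit. MKI67 and TOP2A had log2 fold changes of 0.09 ± 0.10 and 0.06 ± 0.13 (adjusted p = 0.758 and 0.9), and camera gave the cell cycle list an adjusted p of 0.359, or 0.0365 upwards without NT replicate 4. Of 19 p53 targets, PHLDA3 fell from 16.8 ± 1.34 to 8.80 ± 1.87 CPM (log2 fold change −0.93 ± 0.16, adjusted p = 0.0241) and TP53I3 from 32.0 ± 5.08 to 20.1 ± 1.78 CPM (log2 fold change −0.67 ± 0.13, adjusted p = 0.0386). Adjusted over the list alone 3 fell, and in the blocked fit 6 fell and 2 rose. The p53 list had no direction in camera (adjusted p = 0.118, or 0.0378 downwards without NT replicate 4).

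None of 20 genes of microRNA processing and the silencing complex passed edgeR's test over all genes or adjusted over the list alone (4 at an unadjusted p under 0.05; 1 passed in DESeq2). The helicases DDX17 and DDX5, both cofactors of the nuclear processing complex, had log2 fold changes of 0.11 ± 0.09 and 0.08 ± 0.07 (adjusted p = 0.655 and 0.674). In the blocked fit 3 members rose (DICER1, AGO1 and TNRC6A) and 1 fell (AGO4), all 4 chosen after their values were seen. That fit called 18.8% of all genes tested, so these 4 of 20 do not set the list apart. The list was higher in camera with the block (adjusted p = 0.0434; adjusted p = 0.43 with an estimated correlation in the blocked fit) and not without it (adjusted p = 0.0599, or 0.0209 without NT replicate 4 and 0.0235 without shP7 replicate 3). Among 25 microRNA host and long noncoding RNA genes, MIR17HG, the host of the miR-17 cluster, rose from 26.8 ± 2.14 to 40.4 ± 5.87 CPM (SD, n = 3; log2 fold change 0.59 ± 0.12 SE, adjusted p = 0.0402). HOTAIR fell from 1.26 ± 0.261 to 0.413 ± 0.0582 CPM (log2 fold change −1.59 ± 0.33, adjusted p = 0.0418; 0.0503 with limma-voom). Adjusted over the list alone 2 rose and 3 fell, in the blocked fit 3 rose and 6 fell, and camera gave this list no direction (adjusted p = 0.465).

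Of 23 measured interferon-induced genes, 19 had a log2 fold change below 0, with a median of −0.46. IFIT2 fell from 1.90 ± 0.165 to 0.660 ± 0.172 CPM (SD, n = 3; log2 fold change −1.53 ± 0.28 SE, adjusted p = 0.0344), the only member past the test over all genes and adjusted over the list alone. In the blocked fit 11 fell and 1 rose. Camera placed the list lower (adjusted p = 4.14e-04; adjusted p = 0.638 with an estimated correlation), but not without shP7 replicate 4 (adjusted p = 0.157). None of 16 NF-kB and inflammatory genes passed edgeR's test over all genes (3 at an unadjusted p under 0.05; 1 passed in DESeq2); 2 fell adjusted over the list alone and 6 in the blocked fit. IL32 had a log2 fold change of −0.61 ± 0.16 (adjusted p = 0.103), past the test in the blocked fit (adjusted p = 6.60e-06) and in DESeq2 (adjusted p = 0.00595), and NFKB1 had −0.06 ± 0.08 (adjusted p = 0.787). The NF-kB list was lower in camera with the block (adjusted p = 0.00222; adjusted p = 0.43 with an estimated correlation in the blocked fit) and not without it (adjusted p = 0.118, or 0.00805 without NT replicate 1 and 3.90e-04 without shP7 replicate 3).

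CPT1A, which admits fatty acids to mitochondria, fell from 55.9 ± 4.46 to 35.5 ± 4.79 CPM (SD, n = 3; log2 fold change −0.65 ± 0.11 SE, adjusted p = 0.0241), the only 1 of 16 fatty acid oxidation genes past the test over all genes and adjusted over the list alone. The blocked fit had 2 lower. ACSL5, an acyl-CoA synthetase, rose by 0.48 ± 0.10 on the log2 scale (adjusted p = 0.0402), the only 1 of 15 fatty acid synthesis genes past the test over all genes. The count was 2 adjusted over the list alone, and 5 rose and 2 fell in the blocked fit. UGT1A6, a glucuronosyltransferase whose exons are partly shared with other UGT1A genes and whose count is therefore uncertain, fell by 0.65 ± 0.09 on the log2 scale (adjusted p = 0.0119), the only 1 of 19 xenobiotic genes past the test over all genes and adjusted over the list alone. The blocked fit had 4 lower. The xenobiotic list was lower in camera with the block (adjusted p = 0.0434; adjusted p = 0.43 with an estimated correlation in the blocked fit) and not without it (adjusted p = 0.0928, or 0.0211 without NT replicate 4 and 0.0171 without shP7 replicate 3). None of 21 cholesterol synthesis genes, 24 unfolded protein and amino acid response genes, 26 glycolysis and hypoxia genes and 26 ribosomal protein genes passed edgeR's test over all genes; 2, 6, 6 and 0 of them did at an unadjusted p under 0.05, and 0, 1, 4 and 0 in DESeq2. Adjusted over the list alone 2 glycolysis and hypoxia genes rose and 3 fell, and 0 passed in the other 3 of these lists. In the blocked fit 3 glycolysis and hypoxia genes rose and 5 fell.

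Abundant members of those 4 lists did not pass the test over all genes. HMGCS1 had a log2 fold change of −0.17 ± 0.17 (adjusted p = 0.733), ATF4 and SLC3A2 −0.16 ± 0.08 and −0.10 ± 0.09 (adjusted p = 0.358 and 0.673), GAPDH and ENO1 0.11 ± 0.07 and 0.04 ± 0.08 (adjusted p = 0.497 and 0.879), and RPL4 and RPLP0 0.02 ± 0.08 each (adjusted p = 0.936 and 0.948). HMGCS1 and ATF4 fell in the blocked fit (adjusted p = 0.02 and 0.0251), and in that fit 5 cholesterol synthesis genes fell, and 6 unfolded protein and amino acid response genes fell and 1 rose. Camera gave no direction to the lists of cholesterol synthesis (adjusted p = 0.356), fatty acid synthesis (0.309), fatty acid oxidation (0.672), unfolded protein and amino acid response (0.166), glycolysis and hypoxia (0.659) and ribosomal proteins (0.359). Cholesterol synthesis passed downwards without NT replicate 1 (0.0199) or shP7 replicate 4 (0.0293), the unfolded protein list downwards without NT replicate 1 (0.0298), and fatty acid synthesis upwards without NT replicate 4 (0.0337).

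Markers of other cell types did not pass edgeR's test over all genes or adjusted over the list alone (2 fibroblast and endothelial and 0 blood and immune markers at an unadjusted p under 0.05; 0 of either in DESeq2). Of 8 measured fibroblast and endothelial markers, PDGFRA had a log2 fold change of −0.36 ± 0.14 (adjusted p = 0.251) and COL1A1 0.29 ± 0.25 (adjusted p = 0.658); of 5 blood and immune markers, LYZ had −1.04 ± 0.51 (adjusted p = 0.389) and CD14 −0.13 ± 0.19 (adjusted p = 0.833). In the blocked fit PDGFRA and LYZ fell (adjusted p = 2.44e-04 and 1.49e-06) and 1 fibroblast and endothelial marker rose. LYZ also belongs to the secretory intestinal lineages. Camera gave neither marker list a direction (adjusted p = 0.911 and 0.659). The fibroblast and endothelial list had a median of −0.02 and a mean of 0.04. Small noncoding RNAs took a visible share of the counts: RPPH1, the RNA of ribonuclease P, stood at 4872 ± 561 CPM in NT and 5931 ± 1410 in shP7 (SD, n = 3; log2 fold change 0.28 ± 0.16 SE, adjusted p = 0.47) and RMRP at 4108 ± 117 and 4594 ± 666 CPM (log2 fold change 0.16 ± 0.10, adjusted p = 0.509). RPPH1 rose in the blocked fit (adjusted p = 0.011). Of 4 tested genes in the RNA quality list, 0 passed edgeR's test over all genes (1 at an unadjusted p under 0.05; 1 passed in DESeq2), and 1 fell adjusted over the list alone: MALAT1, a nuclear noncoding RNA chosen after its values were seen, at −0.32 ± 0.08 (adjusted p = 0.0891). MALAT1 fell in the blocked fit (adjusted p = 8.00e-04).

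Of 31 lists fixed in advance, 29 had at least 5 tested genes; 11 passed camera with its preset correlation, 4 upwards and 7 downwards. With a correlation estimated per list 0 passed (smallest adjusted p = 0.6, and 0 lists at an unadjusted p under 0.05). The stem cell list lost its call at an estimated correlation of −0.01, under the preset 0.01. Correlation between members therefore does not account for every lost call. Fry tests whether a list moves on balance in a given direction. It also passed 0 (smallest adjusted p = 0.15, with 5 lists at an unadjusted p under 0.05). Its mixed test, which asks whether members change in either direction and gives no direction for the list, passed 19. The blocked fit passed 16 lists, 6 upwards and 10 downwards, with all 11 among them in the same direction. Without shP7 replicate 4 the count was 7.

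**Figure D3:**
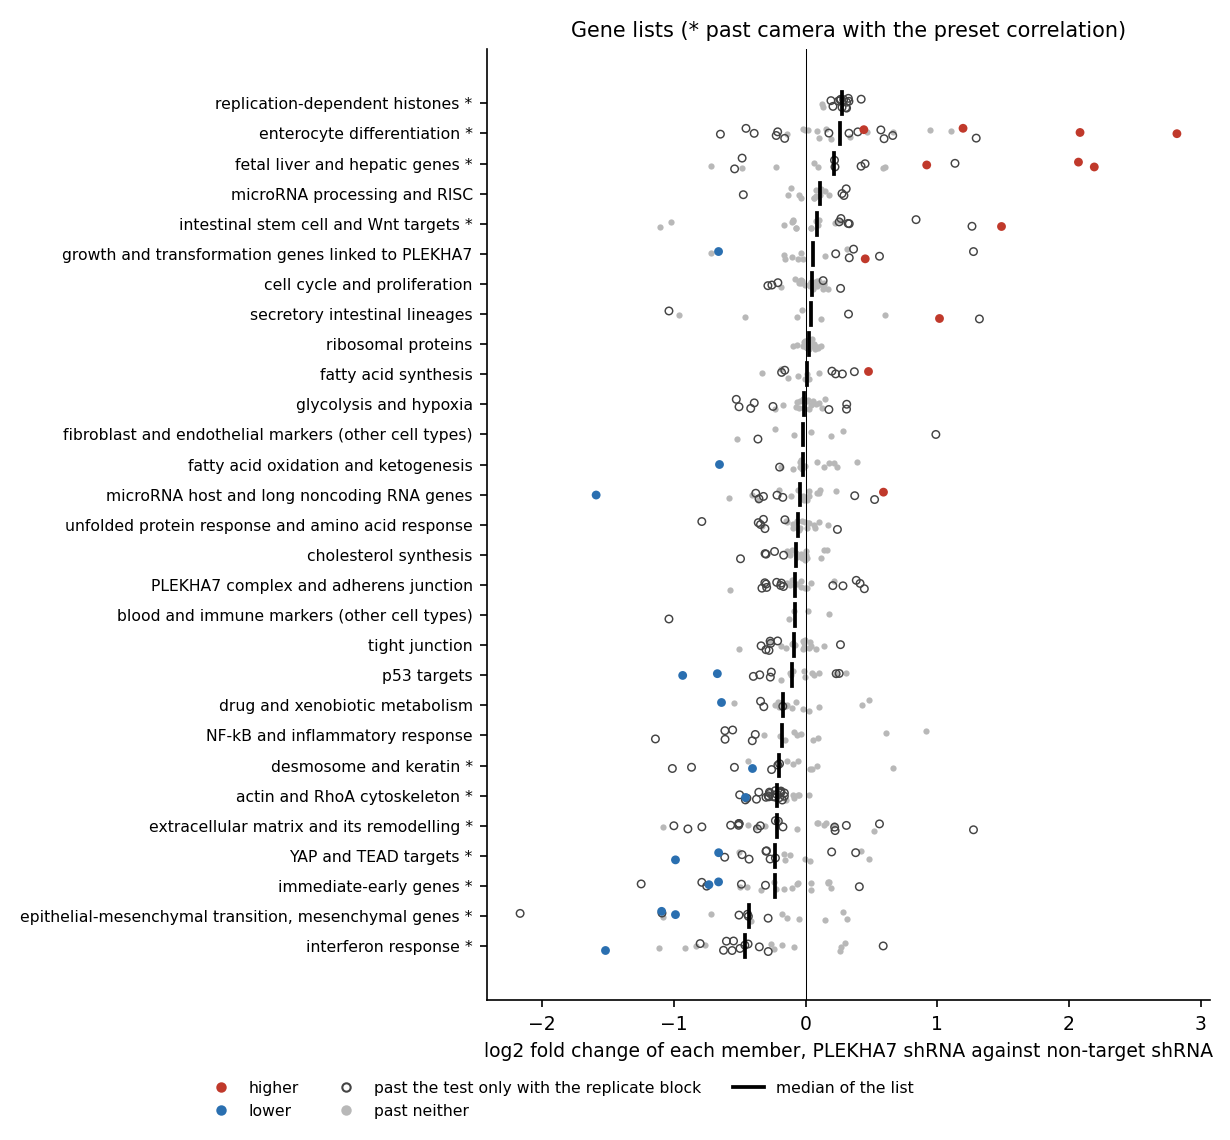
Log2 fold change of shP7 against NT (x axis) for each measured member of the 29 lists tested (y axis), with the median as a black bar; filled red and blue points passed edgeR's test without the block, open points passed with the replicate block alone, and a star marks the 11 lists past camera with the preset correlation. The interferon list has the lowest median (−0.46) and the histone list the highest (0.28).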

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

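The fits with a pair left out of the block, and the block with an estimated correlation, were chosen after seeing the data; the other settings were planned. The alternatives planned for normalized values or for an authors' comparison alone did not apply. No call of a named gene or list reversed under any setting, and the numbers of genes with size factors (277), limma-voom (275), no filter (426) and the stricter filter (269) stayed within 1.5 times of 286, although without the filter the higher genes numbered 120. DESeq2 called 819 genes (249 higher, 570 lower); the cause was not tested. The replicate block called 2865 (1153 higher, 1712 lower), with less spread left after the pair differences were removed, and with pair 1, 3 or 4 left out 2004, 2011 and 2086. Against a fold of 1.5, 1 gene passed (CACHD1, 1 higher and 0 lower; 294 at an unadjusted p under 0.05), and PLEKHA7 at −1.03 no longer did (adjusted p = 0.235; its other alternatives ranged from 8.95e-15 to 0.0726). With libraries left out, and so fewer samples, genes ranged from 0 to 391 (0 to 78 higher, 0 to 313 lower), PLEKHA7 from −1.11 to −0.98, and lists from 7 to 16. Among the 38 genes called that the rule for named genes took besides PLEKHA7, the block and DESeq2 kept 38, size factors 37, limma-voom 34, no filter 34, the stricter filter 34 of 37, the fold of 1.5 kept 1, and left-out single libraries 4 (NT replicate 3) to 32 (shP7 replicate 3). Lists past numbered 0 with an estimated correlation, 0 with fry's directional test and 0 with the block and an estimated correlation (2 at an unadjusted p under 0.05). The replicate block ended no call, and it changed no other call of a list or of a gene named in the text than those given in the results. Counting error alone gives log2 SEs of 0.21 for HOTAIR, 0.19 for CXCR4 and 0.20 for SI, against fitted SEs of 0.33, 0.33 and 0.38, so depth limits these in part; for LYZ it gives 0.04 against 0.51.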

Other observations

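The tests of gene families, of G1/S genes and of every 3' UTR word on the actin, mesenchymal and YAP target genes were chosen after the results were seen. Of 186 families of genes that share a symbol stem, 9 passed camera with the preset correlation, 4 upwards and 5 downwards, all 9 also with size factors and with the block, and none with an estimated correlation (smallest adjusted p = 0.959 with an estimated correlation). The 60 histone genes had a median log2 fold change of 0.32 (adjusted p = 3.81e-17); 0 passed edgeR's test without the block, and 48 rose with it. The numbers of members past edgeR's test are given first without and then with the block. The family names stand for symbol stems such as RAB and COX, which can also take in genes of other functions. As families, annexins were lower by the preset test (15 genes, 2 and 10 fell, median −0.27, adjusted p = 1.89e-05), as were integrin alpha chains (11 genes, 2 and 6 fell, median −0.43, adjusted p = 3.87e-05), RAB GTPases (64 genes, 1 and 19 fell and 0 and 1 rose, median −0.12, adjusted p = 0.00284), septins (12 genes, 0 and 6 fell, median −0.17, adjusted p = 0.0205) and aldehyde dehydrogenases (16 genes, 3 and 4 fell and 0 and 1 rose, median −0.16, adjusted p = 0.0441). Cytochrome c oxidase genes were higher (22 genes, 2 and 7 rose, median 0.12, adjusted p = 7.03e-04), as were NDUFA subunits of respiratory complex I (15 genes, 0 and 7 rose, median 0.18, adjusted p = 0.0178) and MCM genes (11 genes, 0 and 4 rose, median 0.13, adjusted p = 0.049).

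The genes in this paragraph were chosen after their values were seen, and they were not tested as groups. CAV1, CAV2 and PTRF, which build the coat of caveolae, fell with log2 fold changes of −0.97 ± 0.20 (SE, n = 3), −0.72 ± 0.15 and −0.61 ± 0.11. SMAD7 and BAMBI fell by 1.00 and 0.62 on the log2 scale. The actin monomer-binding thymosins TMSB4X and TMSB10 fell by 0.48 and 0.42. COX7C and COX5B rose by 0.74 and 0.44. Each of these genes passed edgeR's test without the block.

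The number of genes that changed, 286, was set against the other splits of the 6 libraries into 3 and 3. Of 10 splits, 1 gave as many, the real one, and the highest of the others gave 0 (at most 1312 genes at an unadjusted p under 0.05); 10 splits are too few for a share under 0.05. Of the 4 splits that part every numbered pair, the blocked fit gave 2865 for the real one and 0 for the others. The number of lists past camera was as large in 3 of the 10 splits, the real one with 11 included, and the highest other gave 16, so chance cannot be excluded for the count of lists. The other 2 splits that gave as many lists, NT 1, NT 3 and shP7 3 against the rest (16) and NT 1, shP7 1 and shP7 4 against the rest (11), part only 1 numbered pair, while the other splits that part every pair gave at most 7. The blocked fit gave 16 lists for the real split, but its lists were not counted for the other splits, so this count does not bear on chance.

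Genes known or predicted as let-7 targets, chosen after their values were seen, were among those that rose (HMGA2 by 1.09, MYCN by 1.39, NR6A1 by 0.80, PRTG by 0.66, LRIG3 by 0.68, CDC25A by 0.42 and LIN28B by 0.45 on the log2 scale), and a candidate explanation is weaker repression through let-7 sites. With those 7 genes left out, 1426 genes with a let-7 site in the 3' UTR were higher by 0.002 before adjustment. After adjustment for 3' UTR length and base composition they were higher by 0.01 ± 0.01 (SE), or 1.17 times the SE. That lies between the bounds of 1 and 2 set beforehand for 3' UTR length or composition as the source. Adjustment did not lower the difference. The site stood at percentile 84.5 of all words of 7 bases, and at 50.5 to 97.6 within 1 SE, where 99 or more was set beforehand for a site effect and under 95 for none. The value of 84.5 itself lay under 95, but the range within 1 SE crossed it. With that spread, weaker let-7 repression and its absence cannot be told apart, though any average rise of genes with a site was small. The let-7 site did not stand out, as that of another microRNA, miR-30, stood at percentile 96.4.

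The actin, mesenchymal and YAP target lists, 64 genes together, had a median log2 fold change of −0.23. The SEs of medians here and in the next paragraph come from resampling genes. They leave out the spread between libraries, which all the genes share. A trend with transcript length or GC is argued against as the whole source, since the median stayed at −0.231 ± 0.029 (SE) after that trend was removed. The 39 members without AATAAAG, the 7-base 3' UTR word that went most with lower levels, had a median of −0.278 ± 0.040. That was under the bound of −0.15 set beforehand by more than its SE, and lower than the −0.182 of the 25 with it. These values argue against a seed match through that word as the source of this fall. The word was picked by its association with lower levels and not from the hairpin, so these medians say nothing about the hairpin's own seed. Over all genes scanned, AATAAAG and the overlapping ATAAAGA went most with lower levels. Their adjusted differences were −0.0443 ± 0.0064 (SE over genes) and −0.0439 ± 0.0075. GAAGAGC, which went most with higher levels, and the overlapping AAGAGCA had 0.0438 ± 0.0093 and 0.0347 ± 0.0088. Whether a seed of either hairpin gave these differences was not tested. The hairpin's sequence is not in the labels. Over all 16242 words, each absent from at least 20 members, the highest median of the members without a word was −0.182 ± 0.033. This SE leaves out the choice of the highest word. The median lay over 2 SE below −0.1, the bound set after the results were seen for a single word as the whole source. It was within 1 SE of −0.15, so a match through another word stays open. A match behind only part of the fall, or outside these genes, was not tested. PLEKHA7 loss itself and the selection of a population stay open as well, since 1 hairpin per group does not separate them.

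Replication-dependent histones, whose transcripts typically lack poly(A) tails, had a median log2 fold change of 0.277 ± 0.021 (SE over resampled genes, 15 genes). Whether the reads of these genes came from transcripts without tails was not tested. Their estimated correlation was 0.84 and HIST1H1E alone had an SE of 0.13, so 0.021 understates the uncertainty between libraries. More RNA without poly(A) tails in the shP7 libraries could raise other such transcripts too. Of these, 244 had a median of 0.059 ± 0.019, under the bound of 0.1 set beforehand. They are mostly small nucleolar and Cajal body RNAs, with a median level of 1.40 CPM. The 141 at 1 CPM or more had 0.036 ± 0.023. In the blocked fit 6 of the 244 rose and 2 fell, and the abundant RPPH1 and RMRP had 0.28 and 0.16. As a set these RNAs did not rise as the histones did. Whether the libraries captured them like histone transcripts was not tested, so this source is not excluded. More cells in S phase may contribute: 22 genes that peak at the G1/S boundary had a median of 0.114 ± 0.033, between the bounds of 0.1 and 0.2 set for the test, so this stays open. Reads shared between near-identical histone genes were not tested.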
